A study of Saccharomyces cerevisiae with 268 samples.

How the data were processed

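The series profiled budding yeast, Saccharomyces cerevisiae, strains that each lack 1 gene for a transcription factor or a related regulator. Per the labels, total RNA of a deletion strain in mid-log growth was labelled with Cy5 and RNA of wild type in mid-log growth with Cy3, so each array had 2 channels. The labels give 268 samples, each a different deletion, and 1 sample per deletion. The number of arrays behind a column, any dye swap, the strain background, the medium, the probes and their positions in each gene, the scanner and the normalization are not given in the sources used here.

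The authors' deposited value table held 1 column per deletion, and its values are treated here as a score without a stated unit. The table's scale, log base, centring and normalization are not given in the sources used here. A plain log2 ratio was not assumed, because the values lay between -8.35 and 8.05, with only 4 values beyond 8 in size, and because 1 whole chromosome stood 2.34 higher in 1 column. Differences are therefore given in score units and never as fold changes. The planned tests had assumed log ratios. The linear model limma was kept, because the scores were signed and spread around 0, and its results apply to the score. Testing a score against 0 uses the wild type RNA as reference and leaves out the spread of wild type itself. The direction was taken from the dyes in the labels, deletion over wild type, so a negative score means less RNA in the deletion strain. Across genes, with values as deposited, 34 of the 35778 pairs of columns correlated below -0.3, and the lowest correlation was -0.42, for TYE7 and SPT10. With each gene centred on its median over strains, as for all other correlations here, the 2.5th percentile of the pairs was -0.366. The labels state the same dye orientation for all columns, so the direction was kept, and a dye swap in single columns was not tested.

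The table had 6419 features. Of these, 5655 carried a systematic name found in the reference gene table of assembly R64, which was used only for gene names and for which genes neighbour each other. The other 764 features were intergenic regions, introns, transposons and dubious reading frames. A gene was tested when at least 80% of columns had a value, which left 5615 genes, of which 3783 had a value in every column. Missing values made up 1.25% of the table, and a column lacked between 0 and 808 features. Column medians ran from -0.40 to 0.17 with a median of -0.15, and the median column SD was 0.84. No 2 columns were identical, and the highest correlation between 2 columns was 0.782. In 6 columns (GCR1, RAP1, REB1, HSF1, ABF1 and MCM1) all values were written with 6 significant digits, which set them apart from the other columns. None of the 6 belongs to a strain set, and an alternative left them out. Several of these genes are essential for growth, and how cells lacking them were obtained is not given in the sources used here. The number of arrays limits the precision, and no spot intensities or background values were used.

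Because every deletion had 1 column, no strain had replicates, and no paired comparison was possible. Groups of strains that lack subunits of 1 complex, or related regulators, were treated as 11 strain sets with 42 strains in all. The sets were fixed from the deleted gene in the label and textbook knowledge before the data were examined. The other 226 strains formed the comparison group. The strains of a set are different genotypes, so a p-value rests on the spread between strains. That spread was pooled over all columns and comes mostly from the 226 strains, so a set's own spread hardly enters. For SER3 in the SAGA set, the SD between the 5 strains was 3.58 and the SE of the difference 0.56. Technical error and the spread between cultures of 1 strain are mixed into the spread between columns and cannot be estimated apart. Each set was compared with the 226 strains by limma, fitted over all columns with 1 mean per set and moderated by eBayes, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The value of a deleted gene was masked in its own strain. Of the same model, 2 contrasts between sets were tested. Tests and alternatives were planned before the data were examined, except where the closing parts say otherwise.

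For 44 gene lists fixed before the data were examined, the median of a list's genes was taken in each strain. These medians were compared between a set and the 226 strains by a two-sided exact Mann-Whitney test, for 20 pairs of set and list named before the data were examined and for all 484 pairs. For 91 pairs of a regulator and the list it is known to control, the list median in the strain lacking the regulator was ranked among the 268 strains. This gives a two-sided exact p of at least 0.00746, and it describes where 1 column stands and is no test over replicates. The deleted gene's own value, the number of genes beyond 1 in size, genes next to a deleted gene, the shift of each chromosome's genes and the correlation between members of a set were also computed. For the shift of a chromosome, each gene was centred on its median over strains, and the median of the chromosome's genes was set against that of all other chromosomes in the same column. A shift was counted when it was at least 0.3 in size and over 6 robust SDs from the median over strains. Similarity within a set was compared with 100000 random sets of the same size.

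The rule for named genes was also fixed before the data were examined. For 6 sets (HAP complex, SWI/SNF, SAGA, Rpd3/Sin3, Mediator tail and Mediator kinase) it takes up to 12 genes each way with the largest differences among those that passed the test and went the same way in every member strain, leaving out genes deleted in the set and features without a gene name. One gene that this rule names is not reported here. For the other 5 sets and the contrasts it takes up to 5 each way, for each list the 4 members with the largest values, and for the breadth of response the 10 broadest and 5 narrowest strains. Genes named outside this rule are said to be so where they appear.

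The model was tested on simulated data drawn from each gene's mean and SD over the 226 strains, with 100 genes changed by 1 score unit and 100 by 2, up and down alike. It recovered 19% and 78% of them for sets of 3 strains, 38% and 91% for sets of 4, and 42% and 93% for sets of 5. It also called 4, 4 and 13 unchanged genes in these simulations of 5615 genes. Each gene was drawn independently, so correlation between genes within a column was absent. These numbers therefore do not give the error on the real columns, where 1 random grouping of 3 strains called 1195 genes. Alternatives were centring each column on its median, quantile normalization between columns, testing against 0 or against all other strains, other filters on missing values, robust moderation, leaving out strains, masking shifted chromosomes and adding principal components as covariates. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.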

Results

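The study profiled RNA from yeast strains that each lacked 1 gene for a transcription factor, a chromatin regulator or a related protein, against wild type RNA on the same 2-channel array. Its stated purpose was to refine a map of which regulator acts on which gene. Each deletion had 1 column of scores and no replicate, with 42 strains in 11 sets and 226 outside every set, and 5615 genes were tested. Values below are scores of the deletion strain over wild type, or differences between such scores, on a scale whose log base and normalization are not given in the sources used here. Each strain is named here by its deleted gene. In 30 columns at least 2 of 4 markers (MET17, STE3, MF(ALPHA)1 and MF(ALPHA)2) were far low, and in DIG1, SIR2 and SDS3 at least 3 of 5 a-specific genes. The reference RNA or the mating type may differ in these 33 columns, so the meaning of their scores over wild type is uncertain.

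The deleted gene itself was low in most columns. Of the 263 strains with a value for their own deleted gene, 116 had the lowest value of that gene among all strains, and 159 lay in the lowest 5%, these included. The median score of a deleted gene in its own strain was -1.87, against -0.14 for the same genes in the other strains. WTM1 had the lowest own value, -7.97. In 14 columns the deleted gene instead lay in the highest 20% of its values: SSN3 (0.53), RPD3 (-0.02), ARG82 (0.89), CAD1 (1.5), SWI5 (2.08), THO2 (0.95), SRB5 (-0.15), NGG1 (1.04), SPT3 (1.47), SPT20 (0.31), YGR067C (1.15), YJL206C (1.23), ABF1 (0.80) and MCM1 (5.03). These are called the columns labelled with that gene from here on. In all, 43 own genes lay above the median of the other strains and 104 lay outside the lowest 5%, so strain names follow the labels, and in those 104 columns the own gene does not show its loss. A probe outside the deleted part checks nothing, and probe positions are not given in the sources used here. For ARR1, SIR3, YRR1, MIG2 and MDS3 the own gene had no value.

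**Figure D1:**
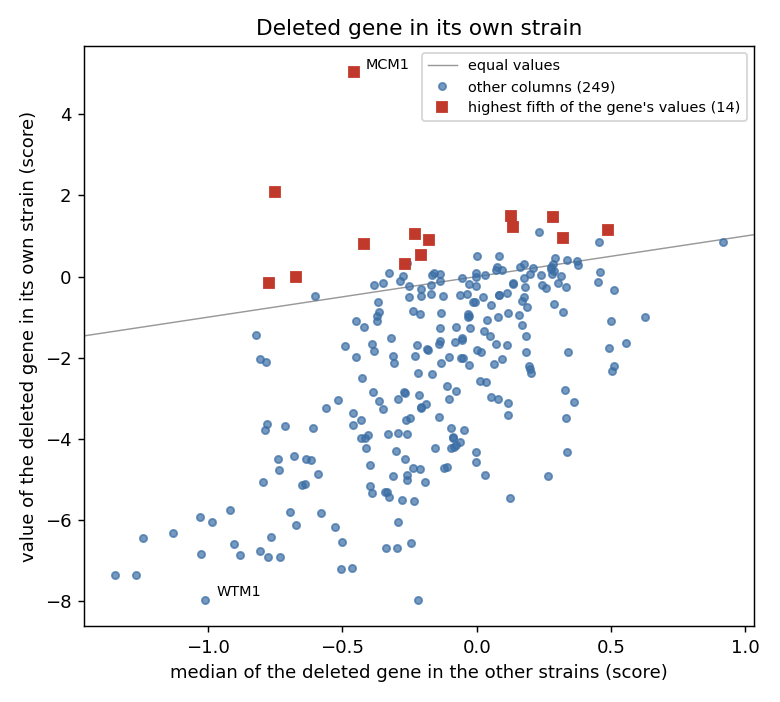
Score of the deleted gene in its own strain (vertical axis) against the median score of the same gene in the other strains (horizontal axis), with 1 point per strain for the 263 strains with a value and a line of equal values. Red squares mark the 14 columns in which the deleted gene lay in the highest 20% of its values, and blue points the other 249, most of them below the line.

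The breadth of the response differed widely between strains. The median strain had 1217 genes beyond 1 in size, with a range from 570 to 2964. The column labelled CST6, the gene of a bZIP factor, had 2964 such genes. TUP1, which lacks a general corepressor, had 2832, and SFP1, which lacks an activator of ribosome synthesis genes, 2666. SNF2 (2603), the column labelled MCM1 (2557), SPT10 (2534), SIN4 (2465), SNF5 (2416), SNF6 (2361) and RAP1 (2350) followed. CST6 itself was at -0.44 in its column, against -0.17 in the others, which does not show its loss. TUP1 was far low in the CST6 column, as given in the closing part, so its breadth cannot be credited to CST6. As a share of genes with a value, the column labelled MCM1 came second (52.3% of 4889, against 50.4% for TUP1), and GCR1 (43.7%) stood above SNF6 (42.2%). The narrowest responses were those of WAR1 (570), TBS1 (591), the column labelled RPD3 (619), HST3 (622) and IBA57 (637). In 243 strains more genes lay below -1 than above 1. Centring each gene on its median over strains lowered the median to 768 genes.

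To see which regulator acts on which known pathway, the median score of a pathway's genes in the strain lacking its regulator was ranked among all strains. In 16 of 91 pairs the strain was the most extreme of all strains, where chance gives 0.679. Each of the 16 had a two-sided exact p of 0.00746, the smallest possible, and an adjusted p of 0.0424 (Benjamini-Hochberg), with the list lowest in 8 and highest in 8. Quantile normalization between columns raised the number past the threshold from 16 to 28. Each pair rests on 1 column, so the ranks have no replicate check. The own gene was outside the lowest 5% in ARG80, OPI1, YAP1, SUM1, CHA4 and BAS1.

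Genes held down by repressors were high in several of these strains. Galactose genes had a median of 7.78 without GAL80, the galactose repressor, against a median of 0.14 and an SD of 0.33 in the other strains, and GAL1, GAL7 and GAL10, which break down galactose, stood at 7.98, 7.85 and 7.78. Ribonucleotide reductase genes had a median of 7.55 without RFX1, a repressor of DNA damage genes, with HUG1 at 7.98, RNR2 at 7.58 and RNR3 at 7.52, against -0.28 (SD 1.04) in other strains. Phospholipid genes reached 4.12 without OPI1, the repressor of that pathway, against -0.29 (SD 0.46), and all 13 stood above their own medians. INO1, which makes inositol phosphate, was at 8.05, the inositol transporter gene ITR1 at 6.72 and CHO1, for phosphatidylserine synthesis, at 6.39. Hypoxic genes reached 3.36 without ROX1, their repressor, with HEM13, a haem synthesis gene, at 7.13 and 8 of 10 above their medians. Arginine genes reached 5.73 without ARG80, a regulator of arginine metabolism: the synthesis genes ARG1, ARG8 and ARG3 stood at 7.45, 6.85 and 6.73, and CAR2, a breakdown gene, at -6.98. Their call is lost with the list mean in place of the median (2.97 above the other strains, adjusted p = 0.0591 in the exact rank test).

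The meiotic and silenced gene groups were also high without their repressors. All 14 early meiosis genes stood above their medians without UME6, the repressor of early meiotic genes, with a list median of 3.10 against 0.14 (SD 0.28) and with RIM4, a meiotic RNA-binding protein gene, at 4.56. HOP1, at 5.35, lies on chromosome IX, whose genes were higher by 2.34 in this column. With these masked the list stood 2.64 above the other strains and still passed (adjusted p = 0.0426 in the exact rank test). All 12 middle sporulation genes were above their medians without SUM1, a repressor of that programme, with a list median of 2.12 against 0.07 (SD 0.29), SPR1 at 6.18 and SMK1 at 5.76. The subtelomeric COS genes had a median of 3.13 without SIR2, the silencing deacetylase, against -0.14 (SD 0.67), with COS8 at 4.66 and COS3 at 4.63 and 10 of 12 above their medians. COS genes are closely related copies, and signal shared between them could not be checked.

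Genes driven by activators were low in the other 8 strains. Glycolysis genes had a median of -7.04 without GCR1, the activator of glycolysis, against -0.79 (SD 0.97), and all 14 lay below their medians, with GPM1 at -7.94, ENO1 at -7.89 and ENO2 at -7.86. Ribosomal protein genes had a median of -6.13 in the RAP1 column, against -0.50 (SD 1.14), with 126 of 132 below their medians, RPS12 at -7.39 and RPL14A at -7.36. Per the labels GCR1 and RAP1 are deletions like the others, and their columns are among the 6 written with 6 significant digits. The GCR1 column was also lowest for sterol (-3.82), proteasome (-3.30), phospholipid (-3.20) and ribonucleotide reductase genes (-3.04), and next lowest for ribosomal protein genes (-5.64). The RAP1 column was also lowest for phosphate genes (-5.58) and next lowest for glycolysis genes (-5.79). Low ranks in these columns are thus not particular to the list named. CHA1, the serine and threonine deaminase gene, stood at -7.55 without its activator CHA4, against -0.82 (SD 1.32). Purine and one-carbon genes were at -4.54 without BAS1, an activator of purine synthesis, against -0.56 (SD 0.77), with SHM2 at -6.88, ADE17 at -6.34 and 13 of 14 below their medians. Retrograde genes were at -4.0 without RTG3, which links mitochondrial state to the nucleus, against -0.35 (SD 0.72), with the citrate cycle genes ACO1 at -6.29 and IDH1 at -6.06 and 5 of 6 low. PUT3, the activator of proline use, gave -2.31 against -0.22 (SD 0.61), with PUT2 at -4.69 but PUT1 at 0.06. YAP1, which drives antioxidant genes, gave -2.05 against -0.34 (SD 0.32), with the peroxidase genes GPX2, AHP1 and TSA1 at -6.72, -5.61 and -5.45 and 13 of 15 low. Nitrogen catabolite genes were at -0.89 without GLN3, their activator, against 0.06 (SD 0.34), with GLN1, glutamine synthetase, at -6.06 and 17 of 20 low.

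**Figure D2:**
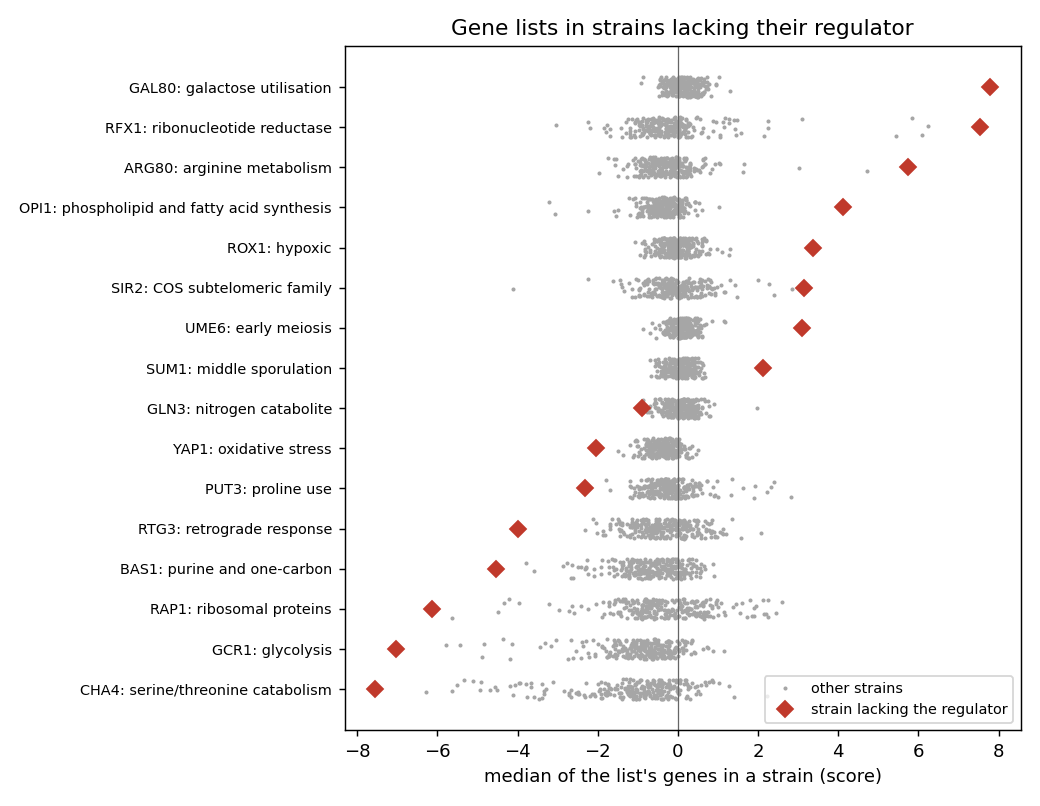
Median score of a gene list in each strain (horizontal axis) for the 16 pairs of regulator and list that passed the adjusted threshold. Red diamonds mark the strain lacking the regulator and grey dots the other strains; the diamonds run from -7.55 (CHA4) to 7.78 (GAL80).

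Several pairs came close without passing. The strain ranked next to the extreme (exact p = 0.0149, adjusted p = 0.0617) for proteasome genes without RPN4, their activator (-2.63, 29 of 31 low), for core histone genes without SPT10, a histone gene activator (-6.07, all 8 low), and for arginine genes without ARG81 (5.68). The same rank held for a-specific genes without SIR2 (-6.95) and for pheromone genes without SIR3 (-1.74). At the high end it held for a-specific genes in the column labelled MCM1 (2.69). Ribosomal protein genes without SFP1 had a median of -4.34 with all 132 low (adjusted p = 0.0937 in the exact rank test), and phosphate genes without PHO2, an activator of phosphate genes, -4.32 (adjusted p = 0.106). Far from the ends lay amino acid synthesis genes without GCN4, their general activator (-0.74, adjusted p = 0.727), retrograde genes without RTG1 (-0.52, adjusted p = 0.853) and phosphate genes without PHO4 (-0.64, adjusted p = 0.485). PHO4 itself was at -0.235 in its column against -0.250 in the others, PHO2 at 0.10 against -0.16, RPN4 at 0.15 against 0.07 and SPT10 at -0.04 against 0.17 (SD 0.56), so these columns do not show the loss of their gene. Galactose genes without GAL4 stood at -0.01, stress genes at -0.57 without MSN2 and at -0.38 without MSN4, and none of these passed.

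Phosphate genes fell together in strains lacking SWI/SNF, a complex that moves nucleosomes. Against the 226 strains outside every set, the acid phosphatase genes PHO5, PHO3, PHO12 and PHO11 differed by -6.30 ± 0.74, -6.25 ± 0.64, -6.14 ± 0.96 and -5.65 ± 0.88 (SE, n = 5 and 226), and the phosphate transporter gene PHO89 by -6.15 ± 1.0. For PHO5 the 5 strains averaged -5.55 ± 1.5 (SD) against 0.75 ± 1.59 (limma, adjusted p = 4.98e-13). Of 15 phosphate genes, 11 fell over all genes tested and 12 adjusted over the list alone. Their list median was -3.12 ± 1.34 (SD, n = 5) against 0.125 ± 0.959 (n = 226), a difference of -3.24, with 5 of 5 strains below the outside median (exact Mann-Whitney p = 2.98e-06, adjusted p = 5.96e-05 over 20 pairs named beforehand). This was the only one of the 20 pairs of set and list to pass. PHO5 and PHO3, and PHO11 and PHO12, are close copies, and signal shared between them could not be checked, so they may not be separate results.

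Other genes that fell included the membrane protein gene YRO2 (-5.63), the cell wall gene TIP1 (-4.98), the amino acid permease gene TAT1 (-4.78), IRC7 (-4.77), for a cysteine lyase, and MOR1 (-4.69). Among 6 a-specific genes, which a cells use for mating, 5 fell, among them BAR1, the alpha-factor protease (-4.53 ± 0.68), MFA1, an a-factor gene (-4.50 ± 0.89), the receptor gene STE2 (-3.65) and AGA2 (-2.82). As a list these did not pass over all 484 pairs (exact Mann-Whitney p = 0.00142, adjusted p = 0.0738). Of genes for sulfate assimilation and methionine, 11 of 21 rose and 1 fell. MET14, adenylylsulfate kinase, differed by 5.21 ± 0.70 (limma, adjusted p = 9.43e-11), MET2, for homoserine acetylation, by 4.52 ± 0.46, the sulfite reductase genes MET10 and MET5 by 3.33 and 3.03, and STR3 by 2.83. NCE103, carbonic anhydrase, rose by 4.86 ± 0.79, SER3, for serine synthesis, by 3.64 ± 0.56, ARG4, for arginine synthesis, by 3.47, CIT2, peroxisomal citrate synthase, by 3.35, and ODC2, a mitochondrial carrier, by 3.03. RTS3 and ICS3 rose by 3.50 and 3.41.

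In all, 1823 genes passed for SWI/SNF, 633 higher and 1190 lower (limma, Benjamini-Hochberg). Stress genes had 1 of 22 lower (0 adjusted over the list alone; list difference -0.24, adjusted exact p = 0.730), and glucose-repressed genes 4 of 15 lower (-0.19, adjusted exact p = 0.358), among them MDH2 (-2.07), ADH2 (-1.81) and ICL1 (-0.86). The calls of MDH2 and ADH2 are lost without SNF6 and that of ICL1 without SNF5, and ADY2 came to pass without SNF11. Quantile normalization left 526 genes, 291 higher and 235 lower, of which 520 were among the 1823. Without the strains that have a shifted chromosome, SWI3 and SNF6 among them, 847 genes passed.

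**Figure D3:**
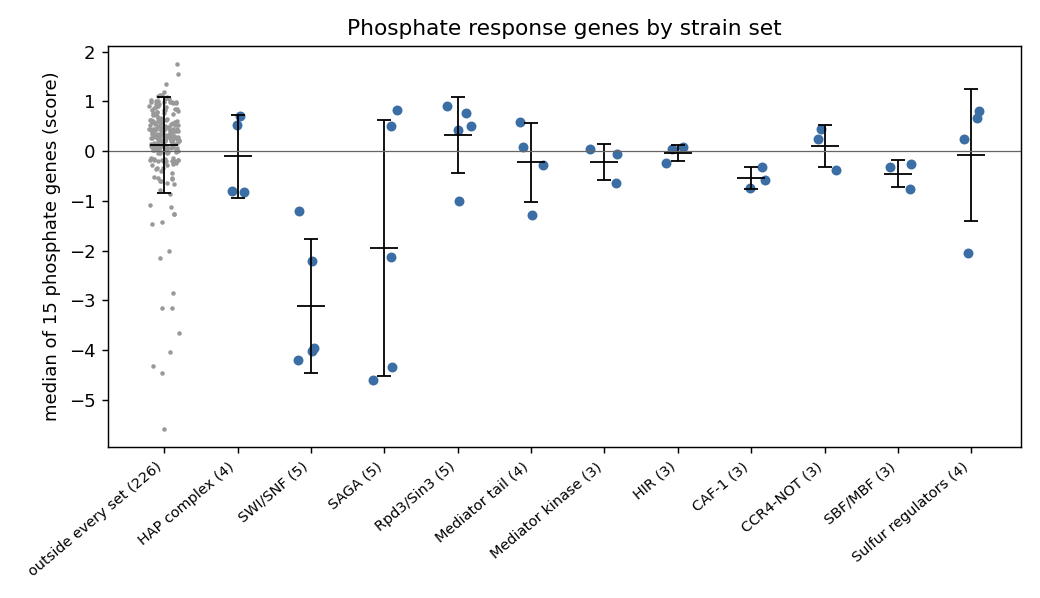
Median score of 15 phosphate genes (vertical axis) in each strain, by strain set and in the 226 strains outside every set, with bars for mean ± SD. The 5 SWI/SNF strains average -3.12 ± 1.34 and the 226 other strains 0.125 ± 0.959.

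SAGA is a coactivator that acetylates histones, and 562 genes passed for its 5 strains, 189 higher and 373 lower (limma). SER3 rose by 4.25 ± 0.56 (SE, n = 5 and 226; limma, adjusted p = 2.33e-09), SGT2, a cochaperone gene, by 1.93 ± 0.33 and IPL1, the Aurora kinase gene, by 1.61 ± 0.36. YRO2 differed by -4.0 ± 0.78, ARO9, for aromatic amino acid breakdown, by -3.77 ± 0.65 (limma, adjusted p = 1.14e-05), HOR7 by -3.49, AMN1, an antagonist of mitotic exit, by -2.93 and GPP2, for glycerol synthesis, by -2.88. These 8 genes passed without any 1 of the 5 strains. The glucanase gene EXG1 (-2.68), REE1 (-2.35) and TFC3 (1.74), for RNA polymerase III transcription, also passed, but not without HFI1. FIT2, for iron uptake (3.53 ± 1.05), CIT2 (3.09), TPM2, tropomyosin (1.94), TAO3 (1.87), MET6, methionine synthase (1.65), BNI5 (1.64), MTG1 (1.61), DID2 (1.5), the polyamine exporter gene TPO2 (-3.81), CIP1 (-3.28), SPI1 (-2.86), IRC7 (-2.74) and MOR1 (-2.65) passed, but neither without HFI1 nor without the column labelled SPT20. MET6, SPI1, TPO2, TAO3 and CIP1 also lost their calls without the column labelled SPT3, and CIP1 without NGG1.

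Amino acid synthesis genes showed no common direction in the SAGA strains: 1 of 33 rose (ARG4, 2.15) and 3 fell, among them ILV3 (-1.96) and HIS1 (-1.70), with a list difference of -0.07 (adjusted exact p = 0.725) and the same counts adjusted over the list alone. ARG4, ILV3 and HIS1 lost their calls without HFI1 or SPT20, and ARG1 came to pass without ADA2 or NGG1. Stress genes lay below the outside median in 5 of 5 strains with a difference of -0.56 (adjusted exact p = 0.260), and only SPI1 of 22 passed. In the column labelled SPT3 the alpha-cell genes STE3, MF(ALPHA)2 and MF(ALPHA)1 stood at -7.17, -3.70 and -2.87, and without columns with such markers 373 genes passed. Without SPT20, HFI1, SPT3 or ADA2, the count was 34, 69, 356 or 911, and without the 3 columns whose own gene was high (SPT3, SPT20 and NGG1) it was 31. The own gene was in the lowest 5% in only 1 of the 5 SAGA columns. In the ADA2 column ASG1 was nearly as low as in the ASG1 column, so which deletion it holds is uncertain. Quantile normalization left 55 genes, 41 higher and 14 lower, and leaving out strains with a shifted chromosome left 45.

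Set against each other, SWI/SNF and SAGA strains differed in 160 genes (limma), 37 higher and 123 lower in SWI/SNF. GPP2 averaged 2.86 ± 2.23 (SD, n = 5) in SWI/SNF and -2.75 ± 2.02 (n = 5) in SAGA, a difference of 5.61 ± 0.74 (SE; limma, adjusted p = 3.32e-09). ALD4, aldehyde dehydrogenase, differed by 4.51 ± 1.0, MET2 by 4.26 ± 0.64, the peroxiredoxin gene AHP1 by 3.98 ± 0.78 and MPC2, a mitochondrial pyruvate carrier gene, by 3.13 ± 0.58. TIP1 was lower in SWI/SNF by the largest amount (-6.48 ± 0.97; limma, adjusted p = 3.82e-07), followed by CHO2, for phospholipid methylation (-3.39), SPC110, a spindle pole gene (-3.30), PGI1, for glycolysis (-2.76), and HAC1, the regulator of the unfolded protein response (-2.75). SPC110 lost its call without SNF2, SNF6, SWI3, HFI1, SPT3 or NGG1, HAC1 without SNF6 or HFI1, and ALD4 without SWI3. HAC1 was at -7.05 in SNF6, and without that value the difference was -1.77 and did not pass. Its chromosome VI was shifted there by only -0.55. The count was 676 without SNF11, 44 higher and 224 lower without SPT20, 83 without SNF2, 81 without NGG1, 59 without SWI3, 47 without SNF6 and 42 without HFI1. Quantile normalization left 3 genes, all higher, and 19 were left without strains that have a shifted chromosome. A fit to the 10 strains alone called 0 genes (limma, with 352 at an unadjusted p under 0.05).

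In strains lacking subunits of the Mediator tail, which binds activators, 112 genes rose and 123 fell (limma). TIM13 and MIM1, for mitochondrial protein import, rose by 2.16 ± 0.52 (SE, n = 4 and 226; limma, adjusted p = 0.0102) and 2.12 ± 0.57, HHF1, a histone H4 gene, by 2.58 ± 0.80, TIP1 by 2.52 ± 0.77 and the peroxiredoxin gene TSA1 by 2.08. The ribosomal protein genes RPL22A and RPS20 rose by 2.35 and 2.08, HMF1 by 2.04, YEN1, a nuclease gene, by 2.02, RPB11, for RNA polymerase II, by 1.98, SNU13 by 1.97 and TMH11 by 1.93. RPN2, a proteasome gene, fell by 2.07 ± 0.45 (limma, adjusted p = 0.00612), VMA1, of the vacuolar proton pump, by 2.10 ± 0.46, and the plasma membrane proton pump gene PMA1 by 2.41 ± 0.61. SPC110 differed by -2.59, the elongation factor gene EFT2 by -2.29, the tRNA synthetase gene THS1 by -2.25, PFK1, for glycolysis, by -2.24, RSA4 and SDD3 by -2.11 each, EGT2 by -2.07, the helicase gene DED1 by -2.05 and SSC1, a mitochondrial chaperone gene, by -2.04.

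Among the lists named for the Mediator tail, 1 of 33 amino acid synthesis genes fell (list difference -0.55, adjusted exact p = 0.260; 1 rose and 1 fell adjusted over the list alone), and HIS4 (-1.46) and ARO4 (-1.13) did not pass. Galactose genes differed by -0.21 (adjusted exact p = 0.517) and stress genes by -0.37 (adjusted exact p = 0.661), with 0 genes called in either by limma over the list alone. SIN4 itself was at 0.03 in its column against 0.31 in the others, while HAC1 stood there at -7.65, near its -7.96 in the HAC1 column, and this was not resolved. The own gene was in the lowest 5% only in NUT1. All of the set's 235 calls depended on SIN4: without it 0 genes passed, with 530 at an unadjusted p under 0.05 (limma), while 137 passed without GAL11 and 445 without NUT1. Without GAL11 the calls of HHF1, SNU13, HMF1, TIM13, RPS20, TMH11, RPL22A, TSA1 and MIM1 were lost, without PGD1 those of SPC110, SNU13, HMF1, TSA1 and SDD3, and without NUT1 that of TIP1, while HIS4 and the chaperone gene SSA4 came to pass without PGD1. Quantile normalization left 4 genes, the first 3 principal components as covariates 50, and leaving out columns with low alpha-cell or a-cell markers gave 501.

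For the Mediator kinase module only HXT9, a hexose transporter gene, passed, at 3.04 ± 2.87 (SD, n = 3) against 0.52 ± 0.78, a difference of 2.52 ± 0.50 (SE; limma, adjusted p = 0.00623). SRB8 (-0.92) and SSN2 (-0.63) were not in the lowest 5% in their own columns. Without the column labelled SSN3, in which the deleted gene was high, HXT9 did not pass and 4 other genes did, and 3 genes passed without SRB8 or without SSN2. HXT9 was also the only gene that differed between tail and kinase strains (-3.05 ± 0.66; limma, adjusted p = 0.0382). That call is lost without GAL11, SIN4, PGD1 or SSN3, and 18 genes passed without NUT1, 4 without SSN2 and 2 without SRB8. Stress genes had a list difference of 0.62 in the kinase strains (adjusted exact p = 0.636), with differences of 2.40 for DDR2 and 2.08 for HSP12, and glucose-repressed genes 0.09 (adjusted exact p = 0.730), and limma called 0 members of either list, with 154 of all genes at an unadjusted p under 0.05.

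The Rpd3/Sin3 histone deacetylase set had 25 genes past the threshold, 15 higher and 10 lower (limma). ODC1, a mitochondrial carrier gene, rose by 1.44 ± 0.37 (SE, n = 5 and 226; limma, adjusted p = 0.0427), GET2, for membrane protein insertion, by 1.24, LDO16 by 1.22, SOL2 by 1.14, TDA7 by 1.01 and CMP2, calcineurin, by 0.92. BNA1, for NAD synthesis, fell by 2.01 ± 0.52, the peroxisomal genes DCI1 and ANT1 by 1.45 and 1.43, and FYV12 by 1.20. Of these genes only DCI1 passed without SIN3, and only DCI1 and CMP2 without UME1. BNA1, TDA7 and DCI1 lost their calls without SDS3, and GET2, CMP2, LDO16 and TDA7 without RPD3. GET2 and CHO1 lie on chromosome V, whose genes were higher by 1.08 in SIN3. With shifted chromosomes masked, which removes the SIN3 values of both, GET2 was at 0.76 and did not pass, nor did BNA1, TDA7 or ODC1 (adjusted p = 0.0537, 0.0527 and 0.0527, limma), and CHO1 was at 0.79. Phospholipid genes lay above the outside median in 4 of 5 strains with a difference of 0.34 (exact Mann-Whitney p = 0.0408, adjusted p = 0.260), and CHO1, with a difference of 1.59, passed only adjusted over the list alone. Early meiosis genes differed by 0.21 (adjusted exact p = 0.730), and limma called 0 of 14, also adjusted over the list alone, with 410 of all genes at an unadjusted p under 0.05. In the SDS3 column the a-specific genes STE2 and BAR1 stood at -7.84 and -7.81, and without columns with such markers 46 genes passed. The count was 1 without SIN3, 5 without UME1, 16 without SDS3, 43 without the column labelled RPD3 and 59, CHO1 among them, without PHO23, and 9 with the genes of shifted chromosomes masked. In the PHO23 column MSN2 was nearly as low as in the MSN2 column, so which deletion it holds is uncertain. Quantile normalization left 0 genes (limma, with 304 at an unadjusted p under 0.05).

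CAF-1 deposits histones behind replication forks, and its 3 strains had 140 genes higher and 16 lower (limma, 5612 genes). BNA4 and BNA1, for NAD synthesis, rose by 3.89 ± 0.61 (SE, n = 3 and 226; limma, adjusted p = 1.33e-06) and 3.65 ± 0.67. AGA1, the anchor of the a-agglutinin, rose by 4.09 ± 0.86, HUG1, an inhibitor of ribonucleotide reductase, by 3.69 ± 0.94 and the thiamine gene THI11 by 3.60 ± 0.54, though THI11 has near-identical copies and is uncertain. SPO13, a meiosis gene, differed by -2.92 ± 0.48 with an SD of 3.52 between the 3 strains, REE1 by -2.37, the transporter gene AQR1 by -2.29, MIA40, for mitochondrial import, by -2.24 and LYS20, for lysine synthesis, by -2.12. The histone genes lay below the outside median in 3 of 3 strains (list difference -0.97, adjusted exact p = 0.358), with HTB2 differing by -2.18, and 1 of 8 was lower adjusted over the list alone. The COS genes differed by 0.32 (adjusted exact p = 0.358), with 0 of 12 called and 658 of all genes at an unadjusted p under 0.05 (limma). The count was 65 without MSI1, 29 without RLF2 and 16 without CAC2. BNA4, BNA1 and THI11 passed in each case, whereas AGA1 and SPO13 did not pass without CAC2, HUG1 and MIA40 not without CAC2 or RLF2, and LYS20, REE1 and AQR1 not without any of the strains.

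HIR is a second histone chaperone, known to repress histone genes. The histone list lay above the outside median in 3 of 3 HIR strains, at 0.67 ± 1.08 (SD, n = 3) against -0.58 ± 1.37, a difference of 1.25 that did not pass (exact Mann-Whitney p = 0.0884, adjusted p = 0.295). HTA1, HHT1 and HHF1 differed by 2.30, 1.73 and 1.71 and HTB2 by -2.01, of which 1 higher and 1 lower passed adjusted over the list alone. HIR1 (0.05 against 0.20) and HIR3 (0.85 against 0.92) were not low in their own columns. In all, 0 genes passed for HIR, with 356 at an unadjusted p under 0.05 (limma). The column medians of these strains lay lower than outside by -0.155 on average. Without HIR1, 1 gene passed, quantile normalization gave 6 genes, and the first 3 principal components as covariates 15.

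For the columns labelled SWI4, SWI6 and MBP1, whose genes encode parts of the G1 regulators SBF and MBF, 30 genes rose and 4 fell (limma). MBP1 itself was at 0.374 in its column against 0.372 in the others, which does not show its loss. ADI1, for methionine salvage, rose by 3.27 ± 0.67 (SE, n = 3 and 226; limma, adjusted p = 0.00171), the vacuolar protease gene PRB1 by 3.17 ± 0.66, PRY1 by 2.92, ALG14, for protein glycosylation, by 2.78 ± 0.51 and OPI10 by 2.47. The transporter gene PDR18 fell by 1.40, the mitochondrial gene SLS1 by 1.27 and the helicase gene ECM32 by 1.24. Of 19 G1/S genes, RFA1, for replication protein A (1.95 ± 0.44), and CDC45, for replication initiation (1.78 ± 0.43), rose over all genes, and 7 rose and 1 fell adjusted over the list alone. The list lay above the outside median in 3 of 3 strains, by 0.716 (exact Mann-Whitney p = 0.0480, adjusted p = 0.260). Without SWI6 only 3 genes passed, ALG14 among them, and 56 passed without MBP1. SLS1, PRY1 and OPI10 also lost their calls without SWI4, where RNR1 and the G1/S list came to pass, and RFA1, CDC45 and SLS1 lost theirs without MBP1. PRB1 and ECM32 lie on chromosome V, whose genes were higher by 0.79 in SWI6, and without their SWI6 values they were at 2.02 and -0.31 and did not pass. ECM32 was low there, against the direction of the shift. RNR1 also lies on chromosome V, and its call without SWI4 was not tested without its SWI6 value. Column medians of the set lay 0.101 above those outside, and quantile normalization gave 14 genes higher and 5 lower.

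The remaining 3 sets showed few or no calls. The HAP complex is known to activate respiratory genes, and 0 of 33 respiratory chain genes passed for the columns labelled HAP2, HAP3, HAP4 and HAP5 (limma, also adjusted over the list alone, with 422 of all genes at an unadjusted p under 0.05). The list difference was 0.12 (adjusted exact p = 0.730), with list medians of 1.05 in HAP2 and -0.93 in HAP4. No column showed the loss of its gene: HAP2 was at -0.16 against -0.35 in other strains, HAP3 at 0.13 against 0.29, HAP4 at -0.13 against 0.45 and HAP5 at -0.51 against 0.18. Only NFG1 (2.63 ± 0.55) and DSE4 (-2.63 ± 0.56, SE, n = 4 and 226; limma, adjusted p = 0.0107 for both) passed, both chosen here after their values were seen, and not the same way in every strain. Neither passed without HAP2 or without HAP4, and 7 genes passed without HAP3. For CCR4-NOT, which shortens mRNA tails, only PRP21, a splicing gene, passed (1.47 ± 0.30, n = 3 and 226; limma, adjusted p = 0.00773), named here after its value was seen. POP2 (-0.49 against -0.60), NOT3 (0.17 against 0.09) and MOT2 (0.04 against -0.17) all lay above the other strains' median in their own columns. In the POP2 column FKH2 was lower than in the FKH2 column. The few calls may therefore not reflect the labelled deletions. Without NOT3, 0 genes passed (limma, 45 at an unadjusted p under 0.05), and 2 did without MOT2. Stress genes differed by -0.42 (adjusted exact p = 0.636) and ribosomal protein genes by 0.04 (adjusted exact p = 0.892), with 0 members of either called by limma and 122 of all genes at an unadjusted p under 0.05. For CBF1, MET28, MET31 and MET32, regulators of sulfur genes, of which CBF1 and MET28 were not low in their own columns, 0 genes passed, with 61 at an unadjusted p under 0.05 (limma). The sulfur list differed by -0.0008 (exact Mann-Whitney p = 0.892, adjusted p = 0.892), and SAM2, S-adenosylmethionine synthetase, with a difference of 1.76, passed only adjusted over the list alone.

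Strains of the same complex were more alike than random sets of strains in 4 of the 11 sets. The mean correlation across genes was 0.561 for CAF-1 (adjusted p = 0.00181, one-sided permutation test on 100000 random sets), 0.445 for SWI/SNF (adjusted permutation p = 0.00033), 0.270 for the Mediator tail (adjusted permutation p = 0.0308) and 0.186 for SAGA (adjusted permutation p = 0.043). Genes are not independent replicates, and the p-values compare sets of strains. In SWI/SNF, SNF11 correlated with the other strains at only 0.0358 to 0.119 and those among themselves at 0.651 to 0.777, and without SNF11 the mean was 0.687. The SAGA call rests on SPT3, SPT20 and HFI1, which correlated at 0.523 to 0.750. ADA2 and NGG1 lay between -0.248 and 0.0913 with every other SAGA strain. NGG1 was high in its own column, and in the ADA2 column ASG1 was nearly as low as in the ASG1 column. The low correlations may therefore not reflect the labelled deletions. The SAGA mean was 0.106, 0.0632 and 0.0856 without SPT3, SPT20 or HFI1, where its call is lost, and 0.328 and 0.347 without ADA2 or NGG1. The Mediator tail lost its call without GAL11 (0.224), SIN4 (0.304) or PGD1 (0.228). With Spearman's rho, SAGA was at 0.142 (adjusted permutation p = 0.0884) and with the most variable genes alone at 0.219 (adjusted permutation p = 0.0791), so its call is lost with either. HAP (0.034), Rpd3/Sin3 (-0.015), Mediator kinase (-0.018), HIR (0.141), CCR4-NOT (0.136), SBF/MBF (0.191) and the sulfur regulators (-0.086) did not pass.

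Genes next to a deleted gene were low more often than the 5% set as chance. Of 460 adjacent genes with a value, 51 (11.1%) lay below the 5th percentile of their values over strains (one-sided exact binomial p = 1.33e-07), and 12 were the lowest of all strains. YLR358C, next to RSC2, stood at -6.25 against -0.17 in other strains, UBC7, next to MAC1, at -5.76, MRX11, next to SSN3, at -4.48 and STV1, next to STB2, at -4.41. Neighbours were taken by consecutive systematic number. Overlap with the deleted reading frame was not checked, so a low neighbour may itself be partly deleted. Of genes 2 places away, 37 of 484 (7.64%) were as low (exact binomial p = 0.00769).

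In 13 strains the genes of a whole chromosome stood apart, in 16 of 4288 pairs of strain and chromosome, 11 of them higher and 5 lower. The genes of chromosome IX were higher by 2.34 in UME6, where 94.8% of 194 genes lay above their median over strains, and those of chromosome XI by 2.16 in MAL33 and by 1.31 in SRB8. The column labelled ABF1 (II, 1.21) and the strains SWI3 (III, 1.17), SIN3 (V, 1.08), SWI6 (V, 0.79), PHO2 (XII, 0.72), SPT4 (XI, 0.68) and NDT80 (XV, 0.67, and XII, 0.55) followed. Lower shifts were those of the column labelled SPT20 (I, -0.98), the column labelled MCM1 (X, -0.55), SNF6 (VI, -0.55, and XI, -0.44) and SWI3 (XI, -0.39). No test was made, since each strain had 1 column. Both arms passed the same rule in 6 of the 16 pairs.

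**Figure D4:**
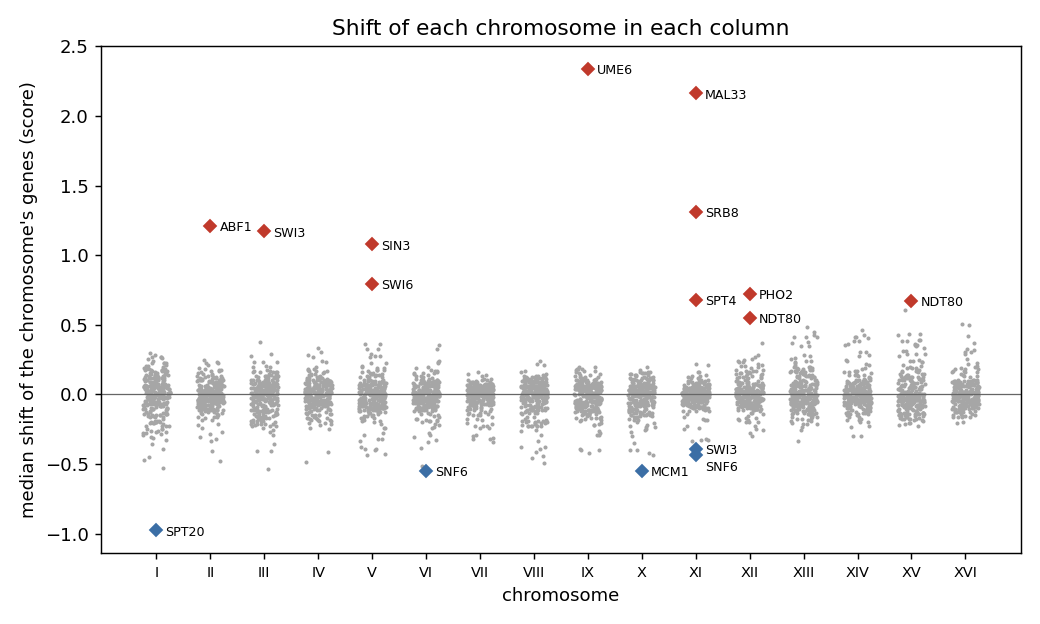
Median shift of the genes of each of the 16 chromosomes (horizontal axis) in each column (vertical axis, score units), each gene centred on its median over strains. Diamonds mark the 16 pairs past the rule, the largest being chromosome IX in UME6 at 2.34.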

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

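The tests of technical explanations below were chosen after results were seen, apart from the 2 on whole chromosomes, whose predictions were written before they were run. In each strain set of 4 or 5 strains, the named genes and list medians were searched for 1 strain far from the others by Dixon's test. It marked 22 of 137 results, each mark 1 gene in 1 set. The nominal rate of 1 in 20 would give 6.85. That rate holds for independent and unselected results. Here many genes were picked for large differences and many marks share a column, so 6.85 is not a chance expectation. SNF11 stood apart from the other SWI/SNF strains in 5 genes: MET2 was at 0.0867 in SNF11 and from 4.49 to 5.84 in the others, and PHO3, TAT1, IRC7 and MFA1 were at -2.89, -1.32, -1.20 and -1.36, above all the others. SIN4 stood apart from the other Mediator tail strains in 7 genes, with SNU13 at 3.28 and PMA1, PFK1, VMA1, SSC1, SNZ1 and ILV3 at -7.10, -5.69, -5.36, -5.82, -2.17 and -7.05. In SAGA, HFI1 stood apart in TFC3 (5.10), REE1 (-4.82) and DDR2 (-2.27), and ADA2 in TSL1 (0.60). In Rpd3/Sin3, SIN3 stood apart in SOL2 (2.32), HOP1 (3.08) and INO1 (6.33, with the others from -0.19 to 0.27), and SDS3 in DCI1 (-4.77). HAP3 stood apart in ATP1 (1.0), and CBF1 among the sulfur regulators in MET22 (-4.73).

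Differences between 2 sets were marked where their own contrast passed (limma, Benjamini-Hochberg). Mediator tail and kinase differed in 1 gene, HXT9 (-3.05). SWI/SNF and SAGA differed in 160 genes, among them GPP2 (5.61), ALD4 (4.51), MET2 (4.26), AHP1 (3.98), MPC2 (3.13), TIP1 (-6.48), CHO2 (-3.39), SPC110 (-3.30), PGI1 (-2.76) and HAC1 (-2.75). A signal also stood in features left out of the gene tests: 14 features of the Ty1 and Ty2 transposons had a median of -6.44 ± 2.48 (SD, n = 5) in SWI/SNF strains and -1.37 ± 1.51 (n = 226) outside every set. SNF11 was at -2.01 and the other SWI/SNF strains from -7.70 to -7.37. The difference was -5.07 (exact Mann-Whitney p = 4.41e-05, adjusted p = 0.000485 over 11 sets).

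The first pattern is the count of genes called for a set, set against random groupings of the same strains, the real one counted among the splits. Among the splits drawn for SWI/SNF, no other called as many genes (1823 genes, 1 of 100 splits as large, highest other 321). The same held among those drawn for SAGA (562, 1 of 100, highest other 164). That is the smallest share 100 splits can give, and it argues against chance for the full SWI/SNF set. For SAGA chance was not excluded. A grouping of as many strains, drawn for Rpd3/Sin3, called 747 genes, more than 562. Its strains, SIR2, GCR2, TYE7, PIP2 and GAL4, are all outside every set. SAGA had only 34 calls without SPT20, 69 without HFI1 and 31 without its columns with a high own gene, all below 164. The shares were not adjusted over the sets and contrasts. For a set, groupings were drawn only from its strains and those outside every set, so broad strains of other sets never entered. Few splits called as many as CAF-1 (156, 2 of 100) and the Mediator tail (235, 4 of 100), but a random grouping called 465 and 437. Chance was therefore not excluded for either, and every call for the tail is lost without SIN4. Chance could not be excluded for HAP (2, 24 of 100, 579), Rpd3/Sin3 (25, 10 of 100, 747) or the Mediator kinase (1, 50 of 100, 880). Nor could it for CCR4-NOT (1, 45 of 100, 543) or SBF/MBF (34, 7 of 100, 1195). The same held for tail against kinase (1, 16 of 35, 10) and SWI/SNF against SAGA (160, 21 of 100, 1066). The 1066 genes came from SNF2, SNF5, SNF6 and SWI3 with SPT20 in place of SNF11. The 10 genes came from SRB8, SSN2 and SSN3 with NUT1. Both splits keep most of the real contrast, so these highest counts do not measure chance. For HIR (0, 100 of 100, 703) and the sulfur regulators (0, 100 of 100, 370) the splits cannot decide, since every split calls at least 0 genes. For several sets the highest random grouping called many times the real count. The 1195 genes came from RTF1, CST6 and SFP1, of which CST6 and SFP1 are among the broadest responses. Structure of the samples as a cause was not tested, and what else the strains share stays open.

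The second pattern is a deleted gene that was high in its own column. For SSN3 a mislabelled sample was argued against: MRX11, the gene next to SSN3, was at -4.48, the lowest of all strains and the lowest feature of the column, though SSN3 correlated with SRB8 at -0.242. For SPT3 and SPT20 it stays open: the lower of their correlations with HFI1 was 0.523, above the limit of 0.454, but SNF5, outside SAGA, reached 0.581. A swap between SPT3 and SPT20 would leave that value unchanged. For the other 11 columns no test was made; in the column labelled CAD1, SIR3 was at -4.32. A probe outside the deleted part was not tested, since probe positions are not given in the sources used here.

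The third pattern is the set of 11 chromosomes whose genes were higher together. For an extra copy of the chromosome, each of 4 stretches of it should be shifted by at least 0.5 times the whole. That held in 8 of 11, between the limits set beforehand, and not in ABF1 or in either chromosome of NDT80, so an extra copy stays open. For the authors' normalization, other chromosomes of the same columns should be shifted too, and 7.98% (13 of 163) were by at least 0.5 times as much, which also leaves that open. No DNA measurement was analysed here.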

How the results depend on the processing

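Of the alternatives, those leaving out the 6 columns of other precision, columns with low markers, a shifted chromosome or a high own gene, masking shifted chromosomes, and adding principal components were chosen after the data were seen. No paired analysis was possible because each deletion has 1 column and columns share no pair. Other counts kept within 1.5 times, and the cause was not tested for any change below except where fewer strains or genes were fitted. Array background is not given in the sources used here.

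Counts for HAP, SWI/SNF, SAGA, Rpd3/Sin3, tail, kinase, HIR, CCR4-NOT, SBF/MBF and sulfur regulators under quantile normalization were 5, 526, 55, 0 (304 at an unadjusted p under 0.05, limma), 4, 2, 6, 3, 19 and 3. The contrasts gave 0 for tail against kinase (509 unadjusted) and 3 for SWI/SNF against SAGA, and 28 regulator pairs passed. Against a score of 0, HAP had 162, SAGA 1397, Rpd3/Sin3 245, tail 852, kinase 48, HIR 650, CAF-1 507, CCR4-NOT 63, SBF/MBF 131 and sulfur regulators 16. Against all other strains, HAP had 1, Rpd3/Sin3 9 and tail 152. Centred columns gave kinase 2. Genes with every value gave 0 for kinase (108 unadjusted, limma), CCR4-NOT (58) and tail against kinase (491). A fit to the 2 sets alone gave 0 for both contrasts (456 and 352 unadjusted, limma). Masked chromosomes gave Rpd3/Sin3 9. With 3 components (16.6, 11.8 and 7.93% of variance), HAP had 5, Rpd3/Sin3 68, tail 50, kinase 9, HIR 15, SBF/MBF 79 and tail against kinase 0 (507 unadjusted, limma). Without high own-gene strains, SAGA had 31, Rpd3/Sin3 46, kinase 3 and tail against kinase 0 (404 unadjusted, limma). Without marker columns, HAP had 4, SAGA 373, Rpd3/Sin3 46 and tail 501. Without shifted chromosomes, SWI/SNF had 847, SAGA 45, Rpd3/Sin3 1, kinase 3, SBF/MBF 3, tail against kinase 2 and SWI/SNF against SAGA 19. Without the 6 columns, HAP had 4, tail 375, kinase 2 and HIR 3.

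Leaving out each strain gave 2 to 7 for HAP, 1302 to 2122 for SWI/SNF, 34 to 911 for SAGA, 1 to 59 for Rpd3/Sin3, 0 to 445 for the tail, 3 to 4 for the kinase, 0 to 1 for HIR, 16 to 65 for CAF-1, 0 to 2 for CCR4-NOT, 3 to 56 for SBF/MBF and 0 to 0 for sulfur regulators (72 to 120 unadjusted, limma). The contrasts gave 0 to 18 and 42 to 676.

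The median strain had 2873.5 genes beyond 0.5 in size and 768 beyond 1 after centring genes, and 25 adjacent genes lay below the 1st percentile. SAGA similarity was 0.142 with Spearman's rho and 0.219 on variable genes. Leaving out each strain, also chosen after the data were seen, gave similarities of 0.0632 to 0.347 for SAGA and 0.224 to 0.323 for the tail. For ARG80 the list mean stood 2.97 above the median of the other strains. GLK1 in SWI/SNF was 1.42, not past the threshold, and -2.17 with 3 components (limma, adjusted p = 0.0245). Of named genes, 2815 results kept their side of the threshold, 33 came to pass it and 1 turned. The rest lost their call, 71 of them under quantile normalization, 42 without shifted-chromosome strains, 27 without high own-gene strains, 25 without SIN4 and 24 with components. Under quantile normalization 114 results on named genes kept their side and 3 came to pass. Many named genes are list members that did not pass at first, and staying uncalled counts as kept. The share of calls kept is therefore lower than these counts of kept results make it look. Of regulator pairs 439 kept theirs, 15 gained and 1 lost it, and of set and list pairs 198 kept theirs and 1 gained it.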

Other observations

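The lists and strains in this part were chosen after their values were seen, except where a test is named as planned. Over all 484 pairs of set and list, 7 passed (exact Mann-Whitney, adjusted over all pairs). In SWI/SNF strains the sulfur genes had a list difference of 1.16 (adjusted p = 0.000124), with SUL2, a sulfate permease gene, higher by 3.30 ± 0.32 (SE, n = 5 and 226; limma). M/G1 genes, used by daughter cells after division, had a difference of -2.39 (exact Mann-Whitney, adjusted p = 0.00164) and 8 of 10 fell, among them SCW11 (-3.85), EGT2 (-3.80) and the chitinase gene CTS1 (-2.48). Glycolysis genes had a difference of -2.10 (exact Mann-Whitney, adjusted p = 0.00164) and 13 of 14 fell, with ENO2 at -3.26, ENO1 at -3.26 and PDC1 at -2.47. CHA1 fell by 3.34 (exact Mann-Whitney, adjusted p = 0.00132). The aromatic amino acid breakdown genes ARO9 and ARO10 fell by 3.89 and 3.52 in SWI/SNF (exact Mann-Whitney list p, adjusted, 4.7e-05) and by 3.77 and 2.13 in SAGA (adjusted exact p = 0.00907).

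Transposon features, low in SWI/SNF, were high in CAF-1, at 1.94 ± 0.416 (SD, n = 3) against -1.37 ± 1.51, a difference of 3.30 (exact Mann-Whitney p = 0.000176, adjusted p = 0.000969). Single strains stood at the end of a list outside the pairs named beforehand. SDS3 had the lowest a-specific genes (-7.39, next SIR2 at -6.95) and the lowest pheromone genes (-2.61). TAF14 followed RFX1 in ribonucleotide reductase genes at 6.23 (TAF14 itself was at 0.33, and GLN3 at -5.99, lower than the -4.23 of the GLN3 column), and the column labelled MBP1 had the highest G1/S genes (0.84), with MBP1 itself at 0.374 against 0.372 in the others. OLE1, the fatty acid desaturase gene, was lowest in SIN4 (-5.12), and the stress genes were high in the column labelled MCM1 (5.07) and in MGA2 (4.98). Histone genes were highest in ISW2 (3.20) and lowest in the HSF1 column (-6.19), and COS genes lowest in SIN3 (-4.12). In the POP2 column FKH2 was at -5.43, lower than the -4.77 of the FKH2 column, and in the CST6 column TUP1 was at -4.16. In the SNF6 column HAC1 was at -7.05 (-7.96 in the HAC1 column), in ADA2 ASG1 was at -4.96 (-5.11 in the ASG1 column) and in PHO23 MSN2 was at -5.55 (-6.04 in the MSN2 column). These single values had no test.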
